A study of Mus musculus with 4 samples.

How the data were processed

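Total RNA from cultured bone marrow-derived macrophages was prepared with Trizol and a column cleanup and sequenced on an Illumina HiSeq, per the labels' protocols. The 4 libraries are WT NT, WT LPS, KO NT and KO LPS, 1 per group, and each library's group was taken from its title. Per the submitters' processing notes, Bowtie and RSEM were used and the genome was mm10. How messenger RNA was selected, the tools' versions, the gene annotation, the strand setting and any read filter are not given in the sources used here.

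Each deposited table lists genes by NCBI gene identifier with a length, an expected count and an FPKM. The expected count is the authors' RSEM estimate of the reads of a gene, in which a read that fits several genes is split among them, so it need not be whole. Of the deposited expected counts, 78.7% to 79.4% per library were exactly whole. The deposited FPKM is the authors' value of fragments per kilobase and per unit of library size, and the read totals that it implies lie close to the summed expected counts. The deposited length, per the file headers, is a gene length, and of 5537 genes of at least 100 counts it differs between libraries for 1821. Genes without a value are left out of a table: the tables list 14299, 13972, 14351 and 13956 genes in the order given above, 12516 of them in all 4, and no listed FPKM is 0. A gene missing from one table was set to 0 there. FPKM is a share of the reads, so a strong gain of some genes lowers all others, and it is imprecise for very short genes, where 1 read can give several FPKM. Reads split between close copies (families such as Ifit, Oas, Gbp, Cd300 and H2-Q, Hspa1a and Hspa1b, and retrocopies) leave those genes uncertain, as do overlapping genes where counting did not use strand.

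Gene symbols and coordinates were taken from an NCBI RefSeq table of GRCm38.p6, the assembly that mm10 denotes, and the exons of Mki67 and its neighbours from the GENCODE M21 annotation. Of 15935 gene identifiers listed in any library, 15897 matched and 38 did not. Folds were computed as log2 of (FPKM + 1) over (FPKM + 1), for genes of at least 1 FPKM in at least 1 of the libraries compared. Genes at least 2-fold apart on this scale were counted. No test was run, since each group has 1 library. For single genes, the ratio of FPKM was given with an exact 95% interval (Clopper-Pearson, on the share of both libraries' counts, rounded to whole numbers). To show what counting error alone gives, Poisson counts were drawn 50 times from the pooled share of each gene at the libraries' totals. A fold against a library where a gene is not listed is given as a lower bound from a floor of 3 counts per library. These intervals and floors cover counting error only: reads made by PCR are not independent molecules.

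The design, the rule for named genes and 29 gene lists were fixed before the data were examined. For each list the median log2 fold of its measured members was computed in each comparison and placed among 10000 random lists of the same size matched on mean log2(FPKM + 1) in 20 bins. This percentile describes these libraries and is not a test of the conditions. A list with fewer than 3 measured members got no median. The rule named Ezh2 and Lyz2 first, then per comparison the 10 genes with the highest and the 10 with the lowest folds among those of at least 5 FPKM, the 10 on each side over both states and for the difference of LPS responses, up to 4 members per list, and a fixed set of genes (Ezh1, Socs3, Socs1, Tnf, Il1b, Il6, Il12b, Il10, Nos2, Ccl2, Cxcl10, Ifnb1, Traf6, Kdm6b, Cdkn2a). Because it took mostly small RNA genes of a few counts, the same rule was also applied to genes of at least 50 expected counts in 1 of the libraries compared. That limit was chosen after the data were seen, and the names printed come from it unless the text says otherwise. Other members of lists named as examples, such as Suz12, Nfkbia, Fos, Jun, Stat2, Pltp, Ltf, Ccl6 and Ccl9, were chosen after their values were seen. Some genes that the rule names are not reported here.

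The alternatives planned were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, libraries rescaled to equal sums or by their median ratio over genes of at least 1 FPKM in all 4, CPM from the expected counts, size rules of 1.5-fold and 3-fold, other choices of the induced genes, matching in 10 bins and the mean of a list. Added after the data were seen were the limit of 50 expected counts and 3 counts in place of 0.

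The computations were tested on simulated counts. For KO against WT without LPS, 8915 genes of at least 50 counts entered: of 50 genes given a 3-fold change 48 were called at least 2-fold apart, of 49 given a 2-fold change 20, and of 8716 unchanged genes 0. The exact intervals held the true ratio for 95.5% of genes there. Of 50 genes given a 2-fold change, 14 were called for LPS in WT, 11 for LPS in KO and 13 for KO against WT with LPS. At 3-fold the last of these called 46 of 50, and 1 unchanged gene was called for LPS in KO. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Sequence-level questions, such as reads over the floxed exons or over single exons of other genes, were not analysed here.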

Results

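RNA was sequenced from mouse bone marrow-derived macrophages, cells grown from marrow of C57BL/6 mice in medium conditioned with M-CSF, the growth factor that drives macrophage differentiation. The marrow came from wild-type mice (WT) or from mice with a floxed Ezh2 gene and Cre recombinase expressed from the lysozyme M promoter (KO). Ezh2 encodes the main catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Each genotype was left untreated (NT) or given lipopolysaccharide (LPS) over 2 h. LPS is the bacterial ligand of Toll-like receptor 4. Each of the 4 groups had 1 library, so no difference below has a replicate check and no p-value was computed. The labels do not say whether the NT and LPS cells of a genotype came from 1 culture. The total expected count was 5678451 in WT NT, 5635004 in WT LPS, 5668826 in KO NT and 5237782 in KO LPS. Folds are log2 ratios of FPKM + 1, a scale that understates the folds of low genes. The 95% intervals given with some ratios of FPKM are exact binomial (Clopper-Pearson) intervals from the counts. They cover counting error only, not the spread between animals or cultures.

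Ezh2 itself (gene ID 14056, chromosome 6, 47530274 to 47595270 in GRCm38) had a low level in every library, 2.84 FPKM in WT NT, 2.52 in WT LPS, 2.06 in KO NT and 1.29 in KO LPS. These values rest on 43, 38, 31 and 18 counts. Over both states the KO libraries held 0.628 times the WT counts at equal library totals, with an interval of 0.431 to 0.906. The interval of the KO to WT ratio included 1 without LPS (0.725, 0.442 to 1.18) and lay below 1 with LPS (0.512, 0.275 to 0.919). The labels do not name the floxed exons, and a gene-level count includes reads from exons outside a deletion, so the level alone does not give the share of recombined alleles. Lyz2, the gene whose locus drives this Cre and whose fractional counts show reads shared with other genes, stood at 11.6 FPKM in WT NT, 18.8 in WT LPS, 18.6 in KO NT and 22.4 in KO LPS. These levels are low for a gene typical of macrophages, the reason was not settled, and they do not measure Cre activity. The paralog Ezh1 was at 12.2 FPKM in WT NT and 12.8 in KO NT, and at 6.13 and 7.85 with LPS. Of the 11 PRC2 genes measured, 10 were above 0 in KO against WT without LPS, with a median log2 fold of 0.21. The intervals of 5 of them lay above 1, among them Suz12 (13.3 to 16.0 FPKM from WT to KO) and Phf19 (ratio 2.17, 1.30 to 3.72). With LPS 9 of the 11 were above 0, at a median of 0.24. Among matched random lists these medians lay at percentiles 99.16 without LPS and 96.09 with LPS.

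The first comparison asks what 2 h of LPS did to WT macrophages. The inflammatory programme was far higher with LPS. Il1b went from 0.79 to 2207 FPKM, Tnf from 25.2 to 4172, Cxcl2 from 4.24 to 3504 and Cxcl10 from 14.7 to 3472. Il6 went from 0.17 to 132 FPKM, from 1 count to 836, so its ratio of 777 has an interval of 139 to 30700. Ifnb1, which encodes interferon beta, was not listed in WT NT and reached 177 FPKM, at least 249.9-fold higher against a floor of 3 counts per library. Ordered by fold, the 10 genes at the top were Il1b, Cxcl1, Cxcl2, Socs3, Il1a, Cxcl10, Il12b, Ptgs2, Ifnb1 and Tnf. Socs3, a feedback inhibitor of cytokine receptor signalling, went from 0.45 to 573 FPKM, and Ptgs2, the inducible cyclooxygenase, from 0.47 to 273.

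By list, 16 of 17 measured pro-inflammatory cytokine genes and 17 of 20 chemokine genes were at least 2-fold higher in WT with LPS, with median log2 folds of 3.81 and 3.51. All 20 genes of the NF-kB family and its feedback were at least 2-fold higher, at a median of 2.86, for example Tnfaip3 (12.2 to 675 FPKM) and Nfkbia (33.6 to 791). Among inflammatory effector enzymes 15 of 20 passed 2-fold, including Nos2, the inducible nitric oxide synthase, at 0.50 and 28.5 FPKM and Acod1, the itaconate-producing enzyme, at 26.8 and 2422. The type I interferon response was mixed: 18 of 34 genes were at least 2-fold higher and the median was 1.19, with log2 folds of 5.13 for Ifi205, 4.89 for Gbp5 and -0.62 for Stat2. Of 18 immediate early genes, 11 were at least 2-fold higher, such as Egr1 (3.48) and Ier3 (3.44), while Fos and Jun were lower, at log2 folds of -1.71 and -1.61. Each of these 6 lists lay at the 100th percentile of 10000 random lists matched on expression. Jarid2 and Aebp2, accessory subunits of PRC2, were 3.38 and 3.24 times as high, and Kdm6b, a demethylase that acts on H3 lysine 27, went from 1.10 to 16.1 FPKM. The 24 measured cell cycle genes had a median of -0.45, level with the median of all genes (-0.46), while Mki67 among them went from 1.79 to 63.2 FPKM.

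In total, 703 of 10972 genes were at least 2-fold higher and 1886 at least 2-fold lower in WT with LPS. Counting error alone, simulated from the pooled counts, gave about 40.6 higher and 40.4 lower. The median gene was at -0.46, so a fold near that value is no difference from the bulk of genes. When the libraries were rescaled by their median ratio, which centres the median gene (-0.03) and so sets the balance by construction, 1050 genes were higher and 825 lower. Genes of at least 50 expected counts with the lowest folds were Gm7367, a transcribed pseudogene with fractional counts (121.26 in WT NT, not listed in WT LPS), then Cd300lb (113 to 6.20 FPKM), AI467606, Rhov, Zfp36l2 (112 to 9.47), Lyl1, Cebpa (34.5 to 2.35), Gpr146, Rnf144b and Lpar6. Zfp36l2 encodes an RNA-binding protein that promotes mRNA decay, and Cebpa a myeloid transcription factor. The 29 macrophage genes had a median of -0.29, above that of all genes but at percentile 7.05 of random lists of like expression, and with median-ratio scaling the median was 0.19.

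The comparison of LPS with NT in KO asks how cells of the floxed genotype responded. The gene groups that were higher in WT were higher here too. In KO, 732 of 11069 genes were at least 2-fold higher and 1667 at least 2-fold lower, and under median-ratio scaling 1073 and 752. The median gene was at -0.42, or -0.03 with that scaling. Il1b (1.72 to 2035 FPKM), Cxcl1, Cxcl2 (3.28 to 1927), Socs3 (0.83 to 711), Cxcl10, Ptgs2, Tnfsf9, Il1a, Acod1 and Il12b were at the top. Pro-inflammatory cytokines (17 of 18 at least 2-fold higher, median 3.24), chemokines (17 of 20, median 3.68), NF-kB genes (20 of 20, median 3.20) and effector enzymes (15 of 20, median 2.38) were higher with LPS. The interferon list had 17 of 34 past 2-fold and a median of 0.86. With libraries at 0 set to 3 counts, the KO cytokine median became 3.0 and the WT one stayed at 3.81, and over other settings they ran from 1.69 to 5.68 and from 2.55 to 6.50. Cebpa, Zfp36l2, Lyl1, Lpar6, Rhov, Rnf144b and AI467606 were again among the 10 genes of at least 50 expected counts with the lowest folds, joined by Hhex (334 to 11.1 counts), Sesn1 (73.3 to 5.05 FPKM) and Rpl37rt. Rpl37rt was not listed in KO LPS, but its fractional counts show reads shared with other genes, which leaves its fold uncertain. Across 11320 genes the WT and KO folds had a Pearson correlation of 0.87 and a Spearman correlation of 0.81. These are across genes, which are not independent replicates, and the 2 folds come from 4 different libraries.

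**Figure D1:**
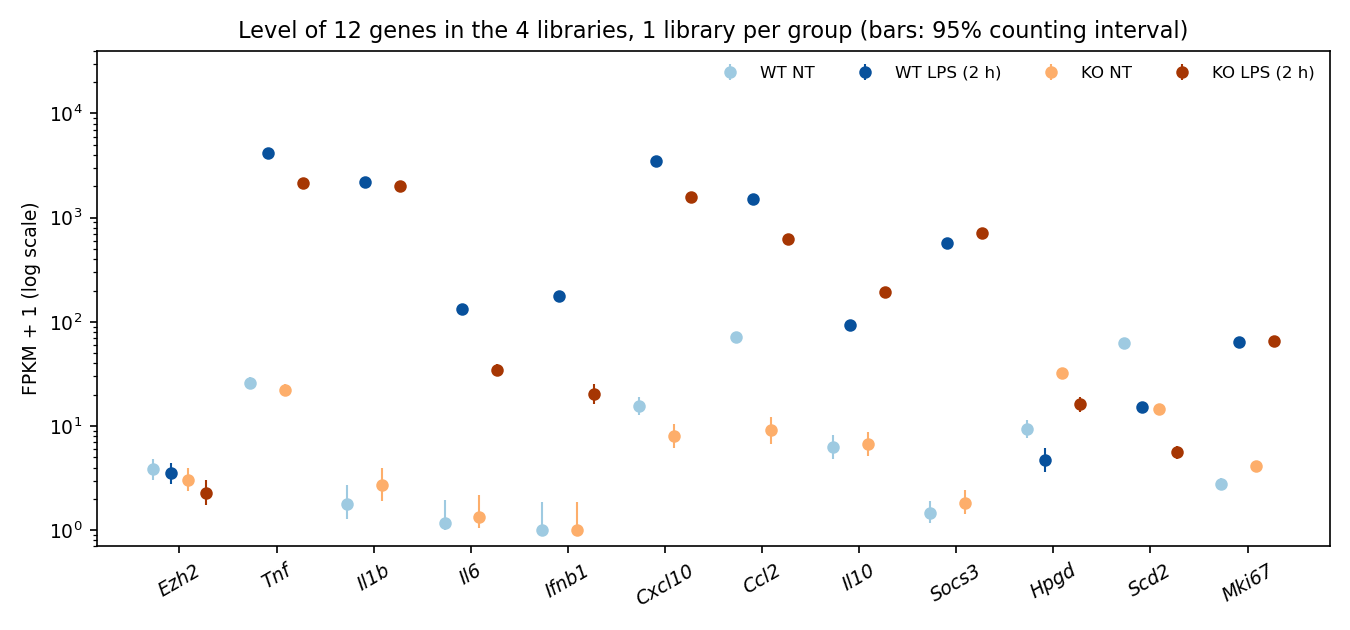
Level of 12 genes in the 4 libraries, as FPKM + 1 on a log axis, with 1 point per library (light and dark blue, WT without and with LPS; light orange and dark brown, KO without and with LPS) and bars for the 95% Poisson counting interval. Ifnb1 reached 177 FPKM in WT LPS and 19.5 in KO LPS, Ccl2 was at 70.0 in WT NT and 8.11 in KO NT, and Mki67 was at 63.2 and 64.7 with LPS.

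The second question is what differed between the genotypes before stimulation. The chemokine list was lower in the KO culture at its median, with 9 of 14 measured members below 0 and 5 above. Ccl2 (gene ID 20296, chromosome 11, 82035577 to 82037452) was at 70.0 FPKM in WT NT and 8.11 in KO NT, a ratio of 0.116 with an interval of 0.0797 to 0.164. Its neighbour Ccl7 (82045712 to 82047525) was at 35.4 and 3.76 FPKM, a ratio of 0.106 (0.0625 to 0.171). Ccl12, in the same cluster, rested on 13 and 3 counts (ratio 0.231, 0.0422 to 0.841). Ccl5 was at 337 and 153 FPKM, while Ccl6 (83.2 to 110 FPKM) and Ccl9 (297 to 325) were higher. Of the 14, 4 were at least 2-fold lower and the intervals of 8 lay below 1, against 3 above. The list's median log2 fold was -0.51, below all 10000 matched random lists, and between -0.74 and -0.12 under other settings.

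Interferon-response genes were also lower, across nearly the whole list. Of 33 measured, 32 were below 0 and the intervals of 30 lay below 1. None passed 2-fold, and the median was -0.47, a 1.39-fold lower level, below all matched random lists. Isg20 (25.8 to 12.6 FPKM from WT to KO), Rsad2 (97.7 to 51.4), Gbp2 (52.3 to 28.9) and Mx1 (77.2 to 45.4) had the most negative folds. Members of the Ifit, Oas and Gbp families have near copies that share reads, which leaves their single values uncertain. Of 21 genes of cholesterol and lipid handling, 14 were below 0 and 7 above, 2 were at least 2-fold lower, and the median was -0.26 at the 0th percentile. The lowest was Scd2, a fatty acid desaturase, at 61.2 and 13.5 FPKM (ratio 0.221, 0.199 to 0.246). Scd1 (-1.07), Fasn (1428 to 687 counts) and Insig1 (-0.85) followed, and Pltp was at 0.65. In the stress list, the median was -0.29 (0th percentile), with Hspa1a (-1.29), which shares reads with the near copy Hspa1b, and the antioxidant genes Gclm (38.0 to 15.8 FPKM), Nqo1 (10.5 to 4.35) and Srxn1 (1571 to 778 counts) lowest.

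The cell cycle list was higher in the KO culture, by less than 2-fold for most members. Of 28 genes measured, 25 were above 0, 2 were at least 2-fold higher, and the intervals of 16 lay above 1 and of 1 below, at a median log2 fold of 0.51 (0.24 to 0.67 under other settings). Mcm5 was at 10.7 FPKM in WT NT and 27.3 in KO NT (ratio 2.56, 2.17 to 3.01), Mcm7 at 8.74 and 20.2, and Tk1, a thymidine kinase outside that list, at 1.71 and 6.93. Markers of neutrophils and their precursors moved the same way: 15 of 18 were above 0, the intervals of 11 lay above 1 and none below, and the median was 0.58. S100a8 (122 to 219 FPKM), S100a9 (156 to 282) and Ltf (17.8 to 27.6) were 1.79, 1.80 and 1.55 times as high. Both lists lay at the 100th percentile. The 30 macrophage genes had a median of 0.12, and fibroblast and stromal markers, all under 4 FPKM, were lower at -0.44 with 7 members. Genes of at least 50 expected counts with the highest folds were Hpgd, which degrades prostaglandins (8.44 to 31.1 FPKM), Plxdc2 (1.18 to 6.11), Tk1, Serpinb6b (2.39 to 8.79), Snhg12, Cd300ld5, Mcm5, Cd300e and Calhm6. The lowest were Gm11545 (11.5 to 0.39), Ccl2, Ccl7, Scd2, Tubb2b (6.21 to 1.18), Ass1 (34.7 to 10.9), Gm6644, Gdf15 (26.6 to 9.44), Pdpn and A530064D06Rik.

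In total, 101 of 10990 genes were at least 2-fold higher and 97 at least 2-fold lower in KO NT than in WT NT, where counting error alone gave about 42.4 and 43.2. The rule for naming genes, fixed before the data were examined, took as the 10 highest here 10 microRNA or small nucleolar RNA genes of at most 4.3 counts, such as Mir5046 and Snora61, and 8 of the 10 lowest were of this kind. Counts and names were therefore also taken among genes of at least 50 expected counts in 1 of the libraries compared, a limit chosen after the data were seen. There 20 genes were higher and 22 lower, where counting error gave 0.04 and 0.14.

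The third comparison sets KO against WT after 2 h of LPS. Ifnb1 was furthest below WT among genes of at least 50 expected counts, and 6th under the rule fixed beforehand, after 5 small RNA genes: 177 FPKM in WT LPS and 19.5 in KO LPS, from 744 and 76 counts, a ratio of 0.110 with an interval of 0.0857 to 0.139. Several cytokines were lower in KO, Il6 at 0.256 times the WT level (0.218 to 0.299), Tnf at 0.512 (0.503 to 0.521), Il12b at 0.648 (0.614 to 0.685) and Il1a at 0.570 (0.541 to 0.601). Il1b was nearly level, at 0.922. Il10, an anti-inflammatory cytokine, was higher, from 92.9 FPKM in WT to 191 in KO (ratio 2.06, 1.87 to 2.26). Of 18 pro-inflammatory cytokine genes 14 were below 0, the intervals of 12 lay below 1 and of 2 above, and the median was -0.64, below all matched random lists.

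Interferon-response genes were again lower in KO with LPS: 33 of 34 were below 0, the intervals of 33 lay below 1, and 7 were at least 2-fold lower. The median was -0.57, at the 0th percentile. After Ifnb1, the lowest were Cmpk2 (526 to 193 FPKM), Isg20 (67.2 to 26.3) and Ifit3 (557 to 241). Rsad2 was at 1544 and 694. Among chemokines, 5 of 20 were at least 2-fold lower, led by Cxcl9 (14.7 to 2.87 FPKM), Ccl2 (1496 to 629), Cxcl10 (3472 to 1568) and Ccl12 (94.4 to 45.7), and Ccl24 was at least 2-fold higher (4.26 to 10.5). The median of the list was -0.39 (0th percentile). Socs1, another feedback inhibitor of cytokine signalling, was at 109 and 64.4 FPKM, Nos2 at 28.5 and 18.9, and Socs3 at 573 and 711. Traf6, an adaptor of Toll-like receptor signalling, was at 7.77 and 8.18 with an interval that included 1, and Kdm6b at 16.1 and 20.5. Cdkn2a, a gene known as a target of Polycomb repression, had 2 counts in KO LPS and was not listed in the other libraries.

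Genes of at least 50 expected counts furthest above WT with LPS were Gm7367 (not listed in WT LPS, at least 18.8-fold higher), Hpgd (3.73 to 15.2 FPKM), Pfkfb3, a regulator of glycolysis (21.5 to 71.1), Sema4c (7.99 to 25.4), Gpr183, Sbno2 (32.8 to 88.6), Mideas, Cd300e, Serpinb6b and Nr4a1. Those furthest below were Ifnb1, Gm11545 (5.08 FPKM and not listed in KO LPS), Cxcl9, Ifit1bl1, Il6, Lhx2, Cd69 (241 to 80.4), Scd2, Cmpk2 and A530064D06Rik. Gm7367 has fractional counts, which show reads shared with other genes. Its fold against WT is therefore uncertain, and the 18.8-fold given need not be a lower bound. The NF-kB list had a median of 0.09 (percentile 93.16) and none of its 20 members past 2-fold. The median of all genes in this comparison was 0.08, so list medians near that value are no difference from the bulk. Cell cycle genes were above 0 in 20 of 23 (median 0.28, or 0.13 to 0.57 under other settings), neutrophil markers in 16 of 19 (0.33, or 0.15 to 0.52), and fibroblast and stromal markers below 0 in 8 of 9 (-0.79). In total, 150 of 10375 genes were at least 2-fold higher and 116 lower, where counting error alone gave about 34.8 and 44.0. With at least 50 expected counts, 41 were higher and 41 lower. With the expected counts scaled to equal totals (CPM), 232 were higher and 116 lower, so 66.7% of the genes past 2-fold were higher, against 56.4% on the FPKM scale. CPM leaves out gene length, so the pseudocount and filter act on another scale, where 11577 genes passed. The change does not show an effect of library totals.

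**Figure D2:**
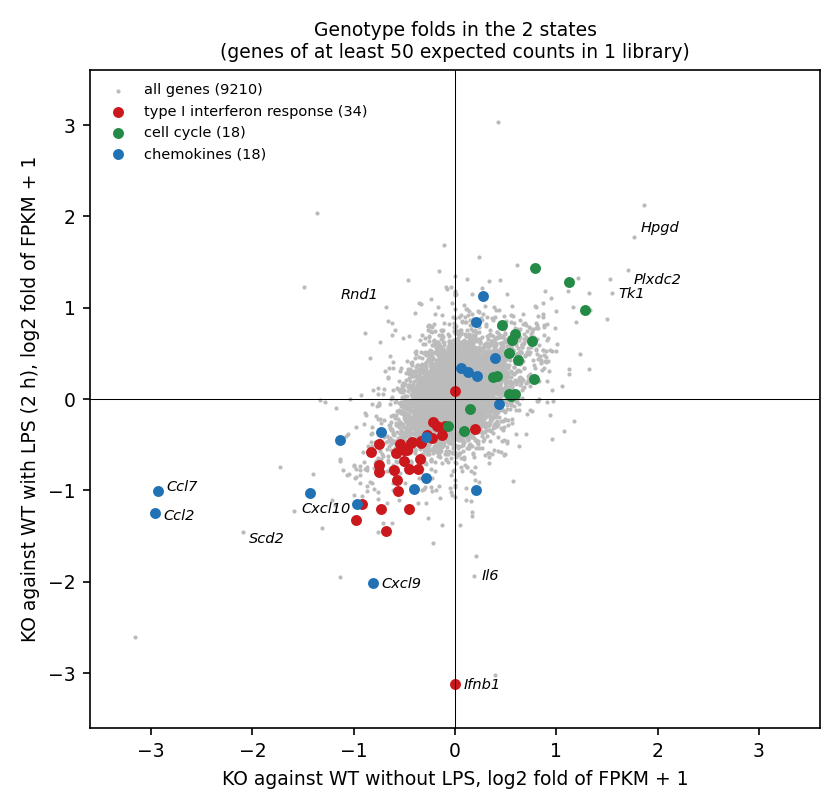
KO against WT log2 folds without LPS (horizontal axis) and with LPS (vertical axis) for 9210 genes of at least 50 expected counts in 1 library, 1 point per gene, with 34 interferon-response genes in red, 18 cell cycle genes in green and 18 chemokine genes in blue. Most red points lie in the lower left part and most green points in the upper right, and the Pearson correlation across these genes was 0.43.

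Some differences between the KO and WT libraries were present in both states. Of 11320 genes, 24 were at least 2-fold higher and 18 at least 2-fold lower in KO both without and with LPS, where independent lists of the same sizes would share 1.34 and 0.994. Among the 9210 genes of at least 50 expected counts these were 10 and 10, against 0.119 and 0.133. The NT and LPS cells of a genotype may come from 1 animal or culture. A difference between animals or cultures would then recur in both states, so the overlap does not tell genotype from culture. The higher ones were led by Hpgd, Plxdc2, Serpinb6b, Cd300e, Cd300ld5, Tk1, Mcm7, Stmn1 (17.1 to 38.1 FPKM without LPS) and Pctp. Those lower in both states were led by Gm11545, Scd2, A530064D06Rik, Ccl2, Ass1, H2-Q9, Ifit1bl1, Gclm, Ccl12 and Ccl7. H2-Q9, Cd300ld5 and Ifit1bl1 belong to families of close copies, and their values are uncertain for that reason. Ass1 encodes argininosuccinate synthase and Gclm a subunit of the enzyme that starts glutathione synthesis. The 2 genotype folds had a Pearson correlation of 0.23 and a Spearman correlation of 0.31 across all 11320 genes.

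**Figure D3:**
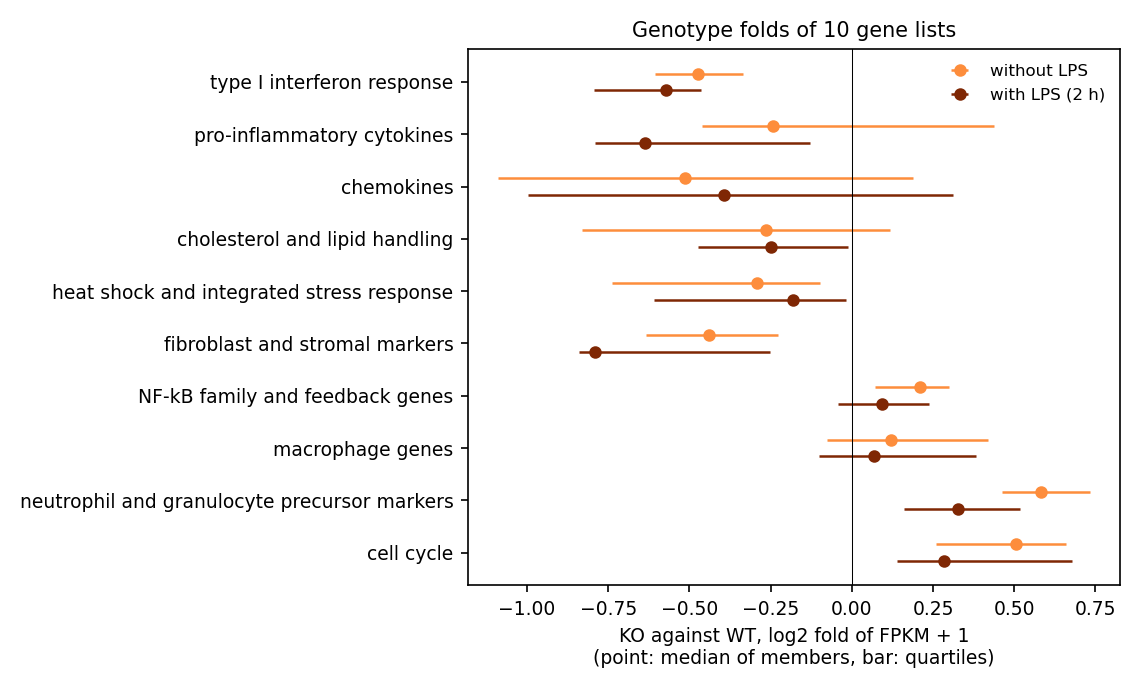
Median KO against WT log2 fold (points) and quartiles of the members (bars) of 10 gene lists without LPS (light orange) and with LPS (dark brown), 1 library per group. The interferon list lies at -0.47 and -0.57, and the cell cycle list at 0.51 and 0.28.

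The last comparison asks whether LPS-induced genes were induced alike in both genotypes. For 695 genes whose mean log2 fold over the genotypes was at least 1, the KO fold minus the WT fold had a median of 0.07, with quartiles of -0.24 and 0.34. The induction was at least 2-fold smaller in KO for 38 genes and at least 2-fold larger for 39. Across all 11320 genes the median difference was 0.05, close to that of the induced genes, with 161 and 215 genes past the same limits. With at least 50 expected counts the numbers were 16 and 22 of 584. Smaller inductions were led by Ifnb1, Il6, Lhx2, Ccng2 (-1.47), Calhm6 (-1.42), Cd69, Sgk1, Cxcl9, Cxcl1 and Ppp1r15a. Larger ones were led by Ccl7 (1.93), Pfkfb3 (1.79), Ccl2 (1.71), Rnd1, Smim3, Hilpda, P2ry2, Adora2b, Gja1 and Ptges. Ccl2 and Ccl7 were lower in KO in both states, and their larger folds start from lower NT levels. Ifnb1 was at least 27.4-fold higher with LPS in KO and at least 249.9-fold in WT. It was not listed in either NT library, so both values are lower bounds and cannot be ranked as inductions. The smaller induction given for Ifnb1 restates its KO against WT difference with LPS. Il6 was 102 times as high in KO (27.9 to 851) and 777 times in WT (139 to 30700), from 2 and 1 counts without LPS, so these intervals overlap. The difference had a median of -0.16 over the interferon list (-0.27 to -0.11 under other settings) and -0.51 over pro-inflammatory cytokines, both at the 0th percentile, and 0.11 over chemokines. For NF-kB genes 10 of 20 differences were above 0. Set side by side, the interferon list lay at -0.47 against WT before LPS and at -0.57 after it. Choosing the induced genes by the WT fold alone gave a median of -0.01, with 64 genes smaller and 16 larger in KO. Choosing them by the KO fold alone gave 0.16, with 14 and 81. A choice by 1 genotype favours genes whose fold there is raised by error, which tilts the difference by construction. These 2 choices therefore decide nothing about the genotypes, and the mean of both was used for that reason.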

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

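The limits applied to gene lengths and to opposite folds, and the tests below on low counts, on a general activation of the WT culture, on the share of macrophages, on differences between cultures, on the other cell cycle genes and on reads of Mki67 shared with a copy were chosen only after the result was seen. Differences of single genes were not tested, since each group has 1 library. Of the genes taken by the naming rule, 9 had counting intervals of the same contrast on opposite sides of 1 in the 2 backgrounds with both log2 folds at least 0.34 from 0. Genes with a smaller opposite fold, such as Marcksl1 (0.34 and -0.18 in KO against WT), were not counted. Gm6644, a transcribed pseudogene with fractional counts, had an LPS log2 fold of -1.55 in WT and 1.17 in KO, a difference of 2.72. Set as KO against WT, Gm6644 was at -1.49 without LPS and 1.23 with LPS, the same difference of 2.72. Mideas had LPS folds of -0.90 in WT and 0.44 in KO, which differ by 1.34.

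For KO against WT, the log2 fold of Rnd1 was -0.68 without LPS and 1.01 with LPS, a difference of 1.69. P2ry2 was at -0.74 and 0.62 (1.36), Adora2b at -0.59 and 0.76 (1.35), and Dusp16 at -0.61 and 0.34 (0.95). Ccng2 was at 0.58 and -0.89 (-1.47), Fos at 0.63 and -0.51 (-1.14), and Klf2 at 0.36 and -0.60 (-0.97). Klf2 rests on 34 to 125 counts per library and Rnd1 on 9.78 counts in KO NT.

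The deposited gene length, which enters each FPKM but was not compared itself, differed with LPS for 3 of 5537 genes of at least 100 counts past a set size limit in both genotypes. It was shorter for each of them, and 0 genes were longer past that limit. In WT the log2 ratio of length was -1.19 for Tsc22d1 (4396 to 1924 bases, with 341 and 339 counts), -0.45 for Ctsc (6447 to 4728) and -0.43 for Aoah (2782 to 2067). In KO the ratios were -1.01, -0.39 and -0.58. Between genotypes 0 genes differed that much in both states.

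More genes were lower than higher after LPS. Induced genes took 3.83% of the reads in WT NT and 22.1% in WT LPS, and that gain alone forces a log2 shift of -0.30 on every other gene, 66.4% of the median fold. With the libraries rescaled by their median ratio 56.0% of the genes past 2-fold were higher (53.7 to 58.3), but that scaling centres the median gene and decides nothing about a common shift. Counting error at low counts is argued against, since among genes of at least 50 expected counts the share was 28.0% (26.09 to 30.01). With a filter of 5 FPKM the excess of lower genes also remained, at 588 higher and 1299 lower (611 and 1166 in KO). Genes of low level that pass this filter stay open, since a pseudocount of 5 gave 485 higher and 452 lower (505 and 399 in KO). The 3-fold rule gave 439 and 459 (469 and 362 in KO). It does not separate size from level, since the pseudocount shrinks the folds of low genes, which pass 3-fold less easily. Reads taken up by induced genes may account for part of the shift, and whether total RNA per cell differed was not measured.

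Interferon-response genes were lower in KO in both states. The tables argue against scaling, since the median without LPS nearest 0 under the other scalings was -0.48. A lower share of macrophages as the whole cause is argued against by the macrophage median of 0.12 (quartiles -0.08 and 0.42), but neutrophil markers at 0.58, megakaryocyte, mast cell and basophil markers at 0.61 and stromal markers at -0.44 leave another difference in culture make-up open. A general activation of the WT culture stays open: 95 genes induced at least 8-fold outside the interferon and chemokine lists had a median of 0.0262 (quartiles -0.23 and 0.26), but the chemokine list left out was at -0.51. Other LPS-induced lists moved apart, with NF-kB and immediate early genes at 0.21 and 0.25 and effector enzymes and cytokines at -0.23 and -0.24. Genotype and any difference between cultures or animals cannot be told apart with 1 library per genotype and state, so an effect of Ezh2 may or may not underlie the pattern.

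Mki67 (chromosome 7, 135689784 to 135716361) went from 104 to 3642 counts with LPS in WT and from 180 to 3464 in KO, which the other cell cycle genes did not follow. The other 23 genes in WT had a median of -0.49 (quartiles -0.63 and -0.21), level with all genes (-0.46), and a maximum of 0.43. In KO the other 27 had a maximum of 0.26. These values argue against more cells in cycle as the cause. They were part of what was noticed, so they are not a separate test. Reads of an overlapping gene are argued against, since Gm45240 lies within the gene on the other strand but exons of other genes cover 0% of its 10061 exon bases. Reads shared with a copy in the authors' annotation are argued against too, since the expected count of Mki67 was fractional in 0 of 4 libraries. A copy outside that annotation, which is not given, would leave the counts whole and stays open. A response of this transcript itself stays open, and no biological explanation was tested.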

How the results depend on the processing

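The limit of 50 expected counts, the setting of libraries at 0 to 3 counts and the 16 list medians taken as leading were chosen only after the data were seen. With 1 library per group no library could be left out. Of 176 alternatives for 16 list medians that lead the comparisons, 174 kept their direction and their side of the outer 2.5% of random lists. The interferon median lay between -0.49 and -0.42 without LPS and between -0.72 and -0.53 with LPS, and the cytokine median with LPS between -0.71 and -0.45. The cell cycle median lay between 0.24 and 0.67 without LPS and between 0.13 and 0.57 with LPS, and the neutrophil median between 0.41 and 0.64 and between 0.15 and 0.52. After LPS the cytokine median lay between 2.55 and 6.50 in WT and 1.69 and 5.68 in KO, the chemokine median between 2.32 and 4.34 and between 2.88 and 5.18, and the NF-kB median between 2.67 and 3.43 and between 2.91 and 3.61. For the cell cycle list in KO against WT with LPS, a pseudocount of 5 gave 0.13 (percentile 96.9), and for neutrophil markers there the mean gave 0.26 (percentile 93.7). Of the alternatives for other list medians, 1205 stayed on their side, 24 moved to an outer side, 62 moved off it and 10, all of medians reported on an outer side, turned their sign. For 7 list medians fewer than 3 members were measured, so no alternative was compared. For single genes 4935 alternatives stayed within the counting interval, 311 moved beyond it and 8 turned their sign. A turned sign was counted only for a gene whose interval excluded 1. Of the alternatives for counts of genes and for the median LPS difference, 72 stayed and 74 moved, and of those for the correlation of the 2 genotype folds 6 stayed and 5 moved. Where the alternative's own construction (fewer genes, another size rule, induced genes chosen in 1 genotype) does not give the cause, the cause was not tested.

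The numbers of genes lower after LPS in WT (1886 as reported) were 452 with a pseudocount of 5 (485 higher), 825 with median-ratio scaling, 4456 at 1.5-fold and 459 at 3-fold, and 439 genes were higher at 3-fold. In KO (1667) they were 2513 and 399 with pseudocounts of 0.1 and 5 (874 and 505 higher), 752 with median-ratio scaling, 4128 at 1.5-fold and 362 at 3-fold, with 1136 and 469 higher at 1.5-fold and 3-fold.

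KO against WT without LPS (101 higher, 97 lower) gave 264 and 198 with a pseudocount of 0.1, 22 and 23 with 5, 40 and 43 with a filter of 5 FPKM, 250 and 207 with libraries rescaled to equal sums, 20 and 22 with at least 50 expected counts, 427 and 336 at 1.5-fold, and 46 and 40 at 3-fold. CPM gave 153 higher. With LPS (150 and 116) the same settings in that order gave 343 and 198, 32 and 37, 65 and 62, 327 and 198, 41 and 41, 589 and 347, and 51 and 49. CPM gave 232 higher. In both states (24 and 18) they gave 88 and 53 with a pseudocount of 0.1, 4 and 3 with 5, 14 higher with 5 FPKM, 47 and 30 with libraries rescaled to equal sums, 10 and 10 with at least 50 expected counts, 134 and 103 at 1.5-fold, and 7 and 5 at 3-fold. CPM gave 37 higher there. Rescaling to equal sums also raised every FPKM against the fixed pseudocount and filter. Its counts therefore do not show an effect of library size alone. CPM leaves out gene length, so the pseudocount and filter act on another scale there too.

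For the LPS response in KO minus WT (38 smaller, 39 larger, median 0.07), pseudocounts gave 85 and 86 (0.1) and 10 and 9 (5), and at least 50 expected counts 16 and 22. Choosing induced genes in WT gave 64 and 16 with a median of -0.0136, choosing them in KO 14 and 81 with 0.16, and a 4-fold limit 13 and 13. The choices in WT or KO alone tilt the difference by construction. Libraries rescaled to equal sums gave 62 larger and a median of 0.13, median-ratio scaling a median of 0.0201, and CPM 25 smaller.

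Signs turned as follows. In LPS against NT in WT, TLR4 pathway components were at -0.0146 with libraries rescaled to equal sums, and alternative activation genes at -0.20 with 5 FPKM and -0.0383 with at least 50 expected counts. In LPS against NT in KO, JAK-STAT genes were at 0.40 with median-ratio scaling and 0.32 as a mean, and the stress list at -0.0329 with no filter, -0.0258 with libraries rescaled to equal sums and -0.0438 in CPM. The antigen presentation mean in KO against WT with LPS was 0.0857, and the neutrophil difference of LPS responses was 0.0136 with at least 50 expected counts. With median-ratio scaling, which lifts every fold after LPS, the LPS fold in WT became 0.16 for Blnk, 0.0652 for Cd4, 0.0699 for Cdkn1c, 0.24 for Ddx3y, 0.0496 for H2-DMa, 0.13 for Kdr and 0.0793 for Vwf, and that in KO 0.14 for Irf8. Depth limits genes of few counts: in KO against WT without LPS counting error alone put about 42.4 genes past 2-fold higher and 43.2 lower, and 0.04 and 0.14 among genes of at least 50 expected counts. Genes under 50 counts did not enter the simulated changes.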

Other observations

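The test of zinc finger genes below was written down before its result was seen, and the other values here were not tested. LPS medians are to be read against the median of all genes, -0.46 in WT and -0.42 in KO. For KO against WT the median of all genes was 0.02 without LPS and 0.08 with LPS. Of the antigen presentation list, 4 class II genes picked after their values were seen were higher in KO without LPS: H2-Aa was at 152 FPKM in WT and 261 in KO, H2-Ab1 at 106 and 175, H2-Eb1 at 61.2 and 116, and Cd74 at 643 and 950. With LPS the pairs were 156 and 246, 107 and 185, 73.1 and 117, and 746 and 1063. The median of the whole antigen presentation list, which also holds class I genes, went the other way, at -0.08 without LPS and -0.15 with LPS. Its mean with LPS was 0.0857, so that direction depends on the summary used. Its LPS medians were 0.14 in WT and 0.04 in KO, with Cd40 from 7.55 to 321 FPKM in WT. Alternative activation genes had KO against WT medians of 0.20 without LPS and 0.27 with LPS, led with LPS by Il4ra (27.5 to 64.7 FPKM), and LPS medians of 0.09 in WT and -0.12 in KO. Negative regulators of signalling were at 0.10 and 0.14 in KO against WT and at 0.73 and 0.50 after LPS in WT and KO, with Dusp1 at 247 FPKM in WT LPS and 469 in KO LPS.

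Genes of the TLR4 pathway had LPS medians of 0.03 in WT and 0.13 in KO (percentiles 99.92 and 99.98). Their genotype medians were 0.05 and 0.12, and Tlr3 was at 16.7 FPKM in WT LPS and 7.35 in KO LPS. MAP kinase genes had LPS medians of 0.53 and 0.90 and genotype medians of 0.10 and 0.14. JAK-STAT genes had LPS medians of -0.16 and -0.01 and genotype medians of 0.01 and 0.19. Immediate early genes were at 0.25 and 0.01 in KO against WT and at 1.27 after LPS in KO, the effector enzymes at -0.23 and -0.10 in KO against WT, the NF-kB list at 0.21 in KO against WT without LPS, and the cytokines there at -0.24. Percentiles in KO against WT without LPS were 99.9 for immediate early genes, 100 for NF-kB genes, 0.13 for effector enzymes and 1.12 for cytokines. Glycolysis genes had LPS medians of -0.33 in both genotypes and genotype medians of -0.10 and 0.05. Cholesterol genes had LPS medians of -0.24 and -0.17 and a genotype median of -0.25 with LPS. Stress genes had LPS medians of -0.39 and 0.01 and a genotype median of -0.18 with LPS. PRC2 genes had LPS medians of -0.23 and -0.39 (percentiles 91.93 and 58.55). H3 lysine 27 demethylases with PRC1 genes had LPS medians of -0.60 and -0.70 (percentiles 36.07 and 9.17) and genotype medians of 0.06 and 0.17. Cell cycle genes in KO and macrophage genes in KO had LPS medians of -0.46 and -0.32, where all genes were at -0.42 (percentiles 57.0 and 8.30), and macrophage genes a genotype median of 0.07 with LPS.

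Developmental Polycomb target genes were largely silent in both genotypes. Of 89 such genes 47 were listed in any library, and 3 to 7 reached 1 FPKM per comparison, with medians of 0.40 and 0.80 after LPS in WT and KO and -0.29 and 0.05 in KO against WT. Cdkn1c, the highest of them, was at 31.4 FPKM in WT NT and 20.3 in KO NT. In KO against WT with LPS the 6 measured members were split, with intervals of 2 above 1 and of 3 below. Hoxb9 (log2 fold 1.05) and Cdkn2b (1.03) were at least 2-fold higher there, and Lhx2 (-1.72) was at least 2-fold lower. Other cell types had few measured markers. In KO against WT without and with LPS, dendritic cell markers were at 0.16 and 0.04, erythroid markers at 0.05 and 0.57, megakaryocyte, mast cell and basophil markers at 0.61 and 0.34, and endothelial markers at -0.77 and -0.51, the last from Kdr (13.0 to 7.23 FPKM without LPS), Vwf (16.8 to 9.07) and Eng. B cell markers were at 0.16 without LPS. Their LPS medians in WT and KO were -0.14 and -0.24 for dendritic cells, -0.51 and 0.07 for erythroid cells, -0.03 and -0.27 for megakaryocytes, mast cells and basophils, -0.37 and -0.19 for endothelium, -0.08 and -0.25 for fibroblasts and 0.08 and -0.19 for neutrophils, and -0.43 for B cells in KO. Of the T and NK cell markers, Cd4 and Cd28 alone reached 1 FPKM, so no median was computed. Sex-linked genes were at 0.03 and 0.12 in KO against WT and -0.38 and -0.30 after LPS.

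A further hypothesis was that genes named Zfp, which encode zinc finger proteins and often have short-lived mRNAs, would be lower after LPS than other genes of like level. In WT 280 such genes had a median of -0.92, against -0.45 for the other genes, at percentile 0 of 2000 matched random lists, and 41.8% of them were at least 2-fold lower, against 16.5%. In KO 287 genes had a median of -0.79 against -0.41. In KO against WT their median was 0.05 without LPS (percentile 73.7) and 0.17 with LPS (percentile 98.8). The values are consistent with the hypothesis, and mRNA half-lives were not measured.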
